A study of Mus musculus with 6 samples.

How the data were processed

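Bone marrow RNA was measured in 6 mouse libraries, 3 of mice that lack the SNORD113-114 cluster (cluster KO) and 3 of wildtype mice. The series design states 3 wildtype against 3 knockout mice, but no label ties a library to a single animal, so p-values measure the spread between libraries. Per the labels, the libraries were made from whole cell extracts with a poly(A) chemistry and a Nextera XT kit that does not keep strand, and the 6 were pooled for sequencing. The submitters' processing notes name bcl2fastq, TopHat2 and HTSeq and the mm10 build. Their versions, the annotation release and the HTSeq counting mode are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, without normalization, in 1 table with 1 column per library. Since the libraries carry no strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies, among them ribosomal protein genes with their pseudogenes and the MHC and Sirpb1 families, have uncertain counts.

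The table holds 47729 genes and 5 HTSeq summary rows, which were left out of library sizes and tests. Of all reads in the table, the summary rows took on average 13.97% (cluster KO) and 16.42% (wildtype) as reads with more than 1 alignment, 8.64% and 10.53% as reads outside genes, and 2.77% and 2.93% as ambiguous reads. Gene names, positions and transcript lengths came from GENCODE M21 on GRCm38, the assembly that mm10 also names, and 47310 of the genes matched by identifier. Transcript length and GC content were the medians over a gene's protein-coding transcripts, or over all its transcripts where it had none of these.

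Groups were taken from the sample titles. The comparison was cluster KO against wildtype with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with its minimum count of 10, a robust quasi-likelihood fit with genotype as the only term, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. The filter kept 15686 genes. The standard error of a log2 fold change was the size of the fitted coefficient divided by the square root of its F value. Normalised read counts are CPM, computed on TMM-scaled library sizes, unless raw counts are named. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 37 lists tested.

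The rule for named genes was fixed before the data were examined. It took every measured gene of the Dlk1-Meg3 locus, then the 12 largest changes in each direction among genes that passed the test without overlap of the libraries. Sex-linked genes, immunoglobulin and T cell receptor segments, genes without a name, pseudogenes and genes with a mean CPM under 1 were left out of those 12. It further took up to 4 members with the smallest p from each called list and from the stem cell, ribosomal, translation, ribosome biogenesis, cell cycle and cell type lists, and the sex-linked genes as a check. Some genes that the rule or the lists name are not reported here. The 38 lists, 1169 symbols in all, covered the locus, cytosolic large and small ribosomal subunits, translation factors, ribosome biogenesis, box C/D snoRNP and snoRNA host or processing factors, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation and mitochondrially encoded mRNAs. They also covered hematopoietic stem cells, early progenitors, quiescence, G1/S, G2/M, neutrophils, monocytes and macrophages, B lineage, plasma cells, T and NK cells, erythroid cells, heme synthesis, megakaryocytes and platelets, basophils with mast cells and eosinophils, dendritic cells, and stroma and endothelium. The others were p53 targets, the unfolded protein and integrated stress response, heat shock, immediate early genes, interferon response, NF-kappaB, mTORC1, glycolysis, antioxidant genes, autophagy and lysosome, imprinted genes, replication-dependent histones and sex-linked genes.

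Library totals ran from 17663369 to 23459168 counts on genes, so that a count of 0 allows up to 3 counts at 95% confidence, 0.128 to 0.17 CPM. Such limits cover counting error only, since the reads carry no molecular identifiers. The test was tried on simulated data for this comparison, with counts drawn from the wildtype means and the real library sizes and 15088 genes tested. It recovered 44 of 94 genes changed 2-fold (46.8%) and 77 of 94 changed 4-fold (81.9%), with 6 unchanged genes called, and it called 4 of 4 shifted lists and 0 of 20 unchanged lists. The changed genes were a far smaller share than the 27.9% of genes called in the real comparison. Recovery at a Benjamini-Hochberg threshold depends on that share, so these rates need not hold for the real test. The simulated genes were drawn independently of each other. The simulation therefore does not show how camera does on lists of correlated genes, such as the large and small ribosomal subunits (estimated correlations 0.78 and 0.94).

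The alternatives were DESeq2 size factors, library size scaling, no count filter, a CPM filter, the replicate number as a block, each library left out in turn, limma-voom with sample weights, the DESeq2 1.42.0 Wald test, other thresholds, a fit without immunoglobulin, T cell receptor, globin and sex-linked genes, camera with an estimated correlation, and fry. Removal of length and GC trends per library by loess, a fit without X, Y and mitochondrial genes, and a fit without cluster KO 3 and wildtype 3 were added after the data had been seen. Shares of reads were compared with an exact permutation test, two-sided, which cannot go below p = 0.1 with 3 libraries against 3.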

Results

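Gene expression was measured by bulk RNA-seq in 3 cluster KO and 3 wildtype libraries of mouse bone marrow. The SNORD113-114 cluster is a group of box C/D small nucleolar RNAs in the imprinted Dlk1-Meg3 region, and the series asks which genes differ once it is lost, with a stated interest in hematopoietic stem cells and translation. The cluster KO libraries held 21424579, 23459168 and 22063846 gene counts and the wildtype libraries 22370022, 17663369 and 19655196. Every pair of libraries within a genotype differed by more than sampling noise, with a chi-square per degree of freedom between 11.3 and 64.2. Globin genes took 0.027 ± 0.006% (SD, n = 3) of the counts in cluster KO and 0.068 ± 0.027% in wildtype libraries. Whether the cells were sorted or depleted of any lineage is not given in the sources used here, so the cell type lists below describe RNA of a marrow sample of unknown makeup.

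The counts could not check the deletion. Rian, the long non-coding host transcript of the region (chromosome 12, 109603940 to 109661716, mm10), had 9, 6 and 3 raw counts in the cluster KO and 11, 5 and 38 in the wildtype libraries, too few for the test. Mirg (109729764 to 109749460) had 1, 1 and 1 counts against 14, 1 and 5. The 23 snoRNA genes annotated from the start of Rian to the end of Mirg had 0 counts in the cluster KO and 1 count in the wildtype libraries, and poly(A) libraries do not capture such RNAs well. Between them, B830012L14Rik (109695586 to 109702587) had 9, 41 and 10 counts against 6, 8 and 0, and Gm37899 (109668869 to 109677585), chosen after its values were seen, had 7, 1 and 0 against 3, 16 and 6, also too few. Elsewhere in the region Rtl1 had 0 counts in the cluster KO and 1 in the wildtype libraries, and Dio3, Mir341, Mir370 and Mir410 had 0 in all 6, where a count of 0 allows up to 3 counts per library. Of the neighbours on the fixed list, Meg3 (109541001 to 109571726) had a log2 fold change of 0.23 (SE 0.39, adjusted p = 0.696, edgeR quasi-likelihood test), Dlk1 1.01 (SE 0.67, adjusted p = 0.286), Begain 0.58 (SE 0.74, adjusted p = 0.588) and Wdr25 0.51 (SE 0.31, adjusted p = 0.242). The other tested genes of the window, looked up after the values were seen, did not pass either: Wars was at 0.73 (SE 0.27, edgeR adjusted p = 0.0673), Slc25a29 at 0.53 (SE 0.40, adjusted p = 0.352) and Slc25a47 at -0.70 (SE 0.57, adjusted p = 0.39). The sizes of the Meg3, Dlk1 and Begain values moved by over 1.5 times without single libraries, to between -0.01 and 0.53 for Meg3, 0.53 and 1.86 for Dlk1 and -0.29 and 0.97 for Begain, and Wdr25 was at 0.16 once length and GC trends were removed.

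Genes of the B lineage and several neutrophil granule genes were higher in cluster KO marrow, while genes of the cytosolic ribosome and of oxidative phosphorylation were lower. These lists passed in camera at its preset correlation but not with an estimated one, where the B lineage had adjusted p = 0.0637 with an estimated correlation, neutrophils 0.366, and both ribosomal subunits and oxidative phosphorylation 0.347. Of 15686 genes tested, 2487 were higher and 1895 lower in cluster KO (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 984 and 453 changed more than 2-fold. Among these 4382 genes, 4310 had no overlap between the libraries of the genotypes, and 46.0% of all tested genes had none, where chance gives 10%. The largest rise by the naming rule was in Cyb561a3, a cytochrome b561 family gene (chromosome 19, 10577172 to 10595961), at 17.1, 29.7 and 41.4 CPM against 1.45, 2.27 and 0.461 CPM (log2 fold change 4.41, SE 0.48, adjusted p = 0.00105, edgeR). Cdh15 (4.01), Rpl3l (3.94), Steap4 (3.85), Olfm4 (3.71), Sirpb1b (3.31), Postn (3.29), Mob3a (3.23), Bmp4 (3.09), Arfgap2 (3.07), Smtnl1 (2.99) and Acta2 (2.95) followed, given as log2 fold changes. Several of these rest on few wildtype reads. Mean CPM was 2.49 against 0.14 for Cdh15 (SE 0.744), 1.96 against 0.13 for Rpl3l (SE 0.815) and 2.21 against 0.14 for Steap4 (SE 0.795). Cdh15, Rpl3l, Steap4, Olfm4 and Bmp4 each had 0 counts in a wildtype library. Wildtype means of Mob3a, Arfgap2 and Smtnl1 were higher, at 0.99, 1.59 and 0.91 CPM. For values this near the floor, the size of a change and its rank are uncertain. The largest fall by the naming rule was in the transcription factor gene Creb5 (log2 fold change -3.85, SE 0.86, adjusted p = 0.0102, edgeR). Creb5 was near the floor in cluster KO, at 0.0914, 0.589 and 0 CPM against 3.8, 2.095 and 4.355 CPM. Thbs1, which encodes thrombospondin 1, changed by -2.57 (SE 0.39), the receptor tyrosine kinase antagonist gene Spry4 by -2.35 (SE 0.45) and the circadian clock gene Per1 by -2.04 (SE 0.24) on the log2 scale. The other falls were Csprs (-2.48), Fabp4 (-2.37), Mir6240 (-2.32), Mir6236 (-2.14), Nectin1 (-2.12), Slc16a12 (-2.09), H2-Q2 (-2.04) and Myl10 (-2.04). Mir6240 and Mir6236 are annotated as microRNA genes. Their CPM ran over all libraries in the order of the share of counts on rRNA genes. Mir6240 was at 6.85, 3.24 and 1.77 CPM against 13.1, 18.0 and 28.2 CPM. The rRNA shares were 0.614, 0.383 and 0.251% against 0.998, 1.08 and 1.44%. Where the reads on these microRNA genes come from was not tested. Sex-linked genes, left out of the naming, made up 4 of the higher and 2 of the lower calls, immunoglobulin and T cell receptor segments 19 and 1, unnamed genes and pseudogenes 129 and 275, and genes with a mean CPM under 1 made up 62 and 41. Without cluster KO 2 the counts were 1258 higher and 742 lower, without wildtype 2 they were 1412 and 944, and without wildtype 3 they were 1303 and 860. Several of the named genes missed the threshold with 1 library left out, given as edgeR adjusted p: without cluster KO 2 Bmp4 (0.0701), Smtnl1 (0.07), Acta2 (0.0593), Csprs (0.0666), Fabp4 (0.0599) and Nectin1 (0.0639), without cluster KO 3 Fabp4 (0.0567) and Nectin1 (0.0565), without wildtype 1 H2-Q2 (0.0556), without wildtype 2 Bmp4 (0.0595), Smtnl1 (0.071), Acta2 (0.0571), Fabp4 (0.108), Nectin1 (0.0819) and H2-Q2 (0.0654), and without wildtype 3 Acta2 (0.0725), Csprs (0.0742) and Nectin1 (0.0622). Over all alternatives the adjusted p of these 7 genes ran from 0.00063, for Bmp4, to 0.109, for Nectin1, and the log2 fold change moved to -6.04 for Creb5 without cluster KO 2, 4.94 for Smtnl1 without wildtype 3, 5.07 for Acta2 without wildtype 1 and -1.22 for Fabp4 without wildtype 2. Without cluster KO 3 and wildtype 3 together it was 1.97 for Arfgap2, 5.64 for Olfm4 and 4.83 for Smtnl1, and with length and GC trends removed it was -1.43 for Mir6236.

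**Figure D1:**
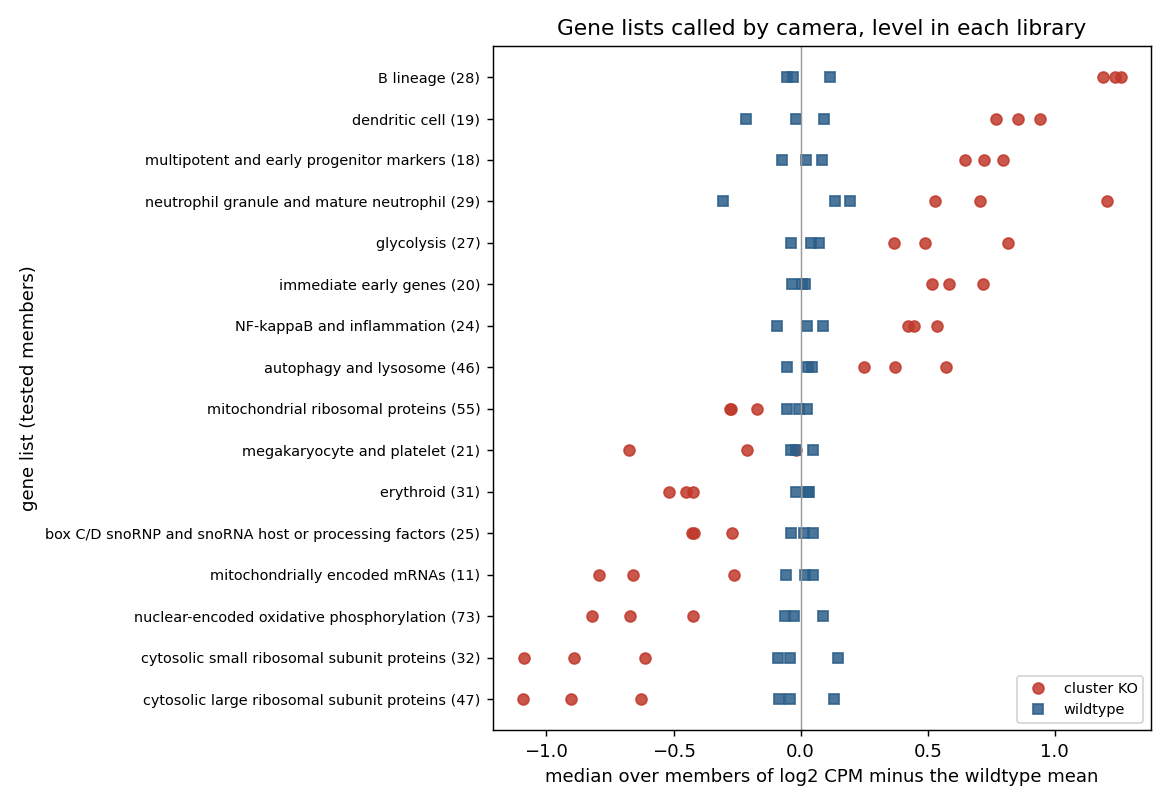
Level of each called gene list in each library, as the median over its members of log2 CPM minus the gene's wildtype mean (circles, cluster KO; squares, wildtype). The B lineage lies at 1.19 to 1.26 in the cluster KO libraries, and the large ribosomal subunit list lies at -0.63, -0.90 and -1.09.

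Ribosomal protein genes were lower across both subunits in cluster KO. Of the large subunit proteins 45 of 47 fell and 0 rose (45 adjusted over the list alone), with a median log2 fold change of -0.86 (camera adjusted p = 1.7e-25). Of the small subunit proteins 32 of 32 fell (32 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.5e-22). Adjusted p = 0.347 with an estimated correlation for both lists, the upper end of camera and fry ranges over the alternatives that start at 1.6e-37 and 1.2e-33. Rpl41 was at 865, 682 and 605 CPM against 1361, 1450 and 1706 CPM (log2 fold change -1.07, SE 0.14, adjusted p = 0.0021, edgeR). Rps12 changed by -1.43 (SE 0.18), Rpl22 by -1.08 (SE 0.14) and Rps3a1 by -0.91 (SE 0.11) on the log2 scale. In the same libraries the share of reads with more than 1 alignment was 13.97 ± 0.66% (SD, n = 3) in cluster KO and 16.42 ± 0.35% in wildtype (exact permutation test, two-sided p = 0.1, the smallest possible). The share of reads outside genes was 8.64 ± 1.38% against 10.53 ± 0.52% (exact permutation p = 0.2). Nuclear and mitochondrial rRNA genes took 0.614, 0.383 and 0.251% of the counts in the cluster KO and 0.998, 1.08 and 1.44% in the wildtype libraries (exact permutation, two-sided p = 0.1), and mt-Rnr1 (-1.87, SE 0.34) and mt-Rnr2 (-1.30, SE 0.24), chosen after their values were seen, fell. Tested genes of the shortest length decile had a median log2 fold change of -0.32, those of the fourth decile 0.32 and those of the longest decile -0.30.

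**Figure D2:**
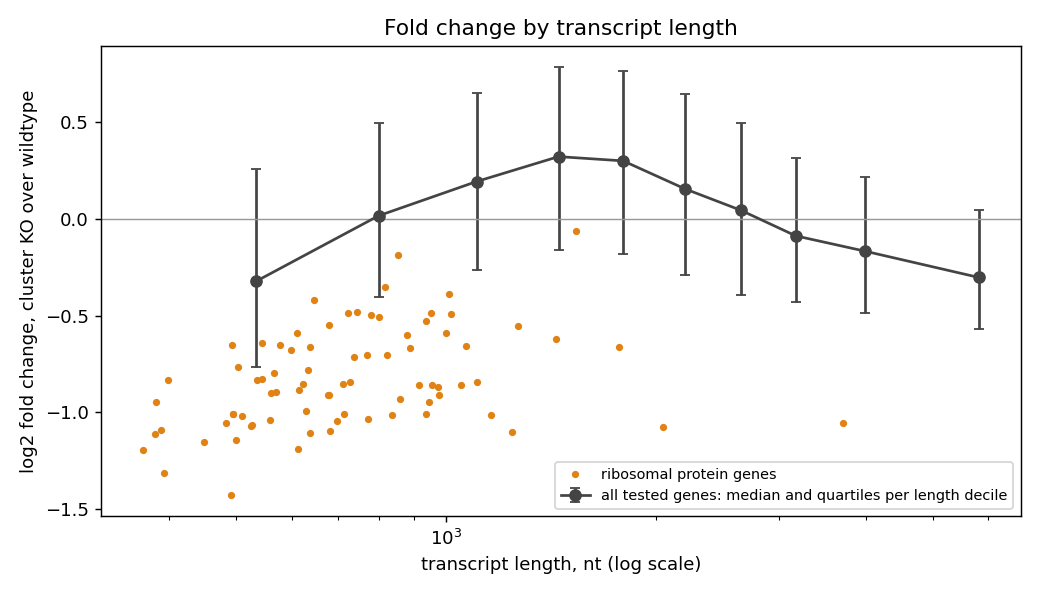
Log2 fold change of cluster KO over wildtype against transcript length in nucleotides (log axis), with the median and quartiles of all tested genes per length decile (black) and each ribosomal protein gene (orange). The 79 ribosomal protein genes have a median of -0.86, and the shortest decile of all tested genes, which holds 39 of them, has a median of -0.32.

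Other parts of the translation machinery moved in both directions. Among box C/D snoRNP proteins and snoRNA host or processing genes 13 of 25 fell and 3 rose (14 and 4 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.00181). Adjusted p = 0.217 with an estimated correlation, against camera and fry values from 2.1e-04 to 0.00492 under the other alternatives. The members with the smallest p were host genes and a box H/ACA protein gene. The list's level was -0.27, -0.42 and -0.43 in the cluster KO and -0.04, 0.01 and 0.05 in the wildtype libraries, in the same order as the share of reads outside genes within each genotype (10.05, 8.59 and 7.29%, and 10.03, 10.50 and 11.06%). Gas5, a host of several snoRNAs, changed by -0.82 (SE 0.11; -0.53 once length and GC trends were removed), Snhg8 by -0.95 (SE 0.15) and the H/ACA gene Nop10 by -0.80 (SE 0.12) on the log2 scale. Of the translation initiation and elongation factors 15 of 48 fell and 8 rose (16 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.202, 0.033 once length and GC trends were removed, range over the alternatives 0.033 to 0.464). The elongation factor gene Eef1b2 fell (log2 fold change -1.04, SE 0.16) and the X-linked Eif2s3x fell (-1.01, SE 0.11), while Eif5a (1.17, SE 0.20) and the helicase gene Eif4a1 (0.85, SE 0.14) rose. Of the ribosome biogenesis genes 13 of 51 fell and 8 rose (14 and 8 adjusted over the list alone), with a median of 0.01, a mean of -0.01 and a camera direction that was down (adjusted p = 0.448). Rrp12 (-1.44, SE 0.25), Ddx21 (-0.73, SE 0.13) and Npm1 (-0.58, SE 0.09) fell and Taf1b (1.04, SE 0.15) rose, on the log2 scale.

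Genes of mitochondrial energy production were also lower. Of nuclear-encoded oxidative phosphorylation genes 52 of 73 fell and 6 rose (53 and 10 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 4.5e-13). Adjusted p = 0.347 with an estimated correlation, against camera and fry values from 4.1e-18 to 0.00752 under the other alternatives. The list's level was -0.42, -0.67 and -0.82 in the cluster KO libraries, at shares of reads outside genes of 10.05, 8.59 and 7.29%, and -0.06, -0.03 and 0.09 in the wildtype libraries, at 10.03, 10.50 and 11.06%. Cox6a1, a subunit of cytochrome c oxidase, changed by -0.95 (SE 0.12) and Ndufa5, of complex I, by -0.99 (SE 0.14) on the log2 scale. Of mitochondrial ribosomal protein genes 23 of 55 fell and 5 rose (27 and 6 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00486). Adjusted p = 0.515 with an estimated correlation, against camera and fry values from 3.6e-04 to 0.04 under the other alternatives. Mrpl52 changed by -1.15 (SE 0.12) and Mrps28 by -0.76 (SE 0.12) on the log2 scale. Of the mitochondrially encoded mRNAs 6 of 11 fell and 0 rose (7 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 0.00225). Adjusted p = 0.437 with an estimated correlation, over a range of alternatives that starts at 1.7e-04, and the list also missed the threshold once length and GC trends were removed (median -0.21, camera adjusted p = 0.158). Genes of the mitochondrial genome took 1.79 ± 0.36% (SD, n = 3) of the counts in cluster KO and 2.85 ± 0.19% in wildtype libraries (exact permutation p = 0.1), and mt-Nd2 changed by -1.08 (SE 0.19) on the log2 scale.

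B lineage genes were higher in all 3 cluster KO libraries. Of the B lineage list 18 of 28 rose and 0 fell (18 adjusted over the list alone), with a median log2 fold change of 1.16 (camera adjusted p = 1.0e-20). Adjusted p = 0.0637 with an estimated correlation, against camera and fry values from 6.9e-33 to 7.3e-04 under the other alternatives. Cd79a, a signalling chain of the B cell receptor, was at 416, 450 and 417 CPM against 97.3, 97.8 and 84.4 CPM (log2 fold change 2.20, SE 0.11, adjusted p = 1.0e-05, edgeR). The surrogate light chain gene Igll1 changed by 1.58 (SE 0.10) and Cd79b by 1.56 (SE 0.11) on the log2 scale. Of the plasma cell list 5 of 14 rose and 2 fell (5 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.123, 0.0138 without wildtype 2, range over the alternatives 0.00949 to 0.722). Mzb1 rose (1.63, SE 0.13) and the immunoglobulin heavy chain gene Ighg2b fell (-2.72, SE 0.27). Of the T and NK lineage 6 of 25 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of -0.11, a mean of 0.02 and a camera direction that was up (adjusted p = 0.448). Trbc1 (0.93, SE 0.12) and Lck (0.90, SE 0.14) rose. Of the dendritic cell list 9 of 19 rose and 0 fell (10 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 1.6e-04). Adjusted p = 0.217 with an estimated correlation, against camera and fry values from 2.1e-06 to 0.00522 under the other alternatives. The risen members included Cd74 (1.44, SE 0.16), H2-Aa (0.99, SE 0.14) and Ly6d (1.18, SE 0.18), which B lineage cells also express.

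Several early progenitor markers rose, and stem cell markers went both ways. Of the multipotent and early progenitor list 10 of 18 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 6.6e-06). Adjusted p = 0.217 with an estimated correlation, against camera and fry values from 2.3e-09 to 0.0016 under the other alternatives. Dntt, the terminal transferase of lymphoid precursors, changed by 1.28 (SE 0.10), Cd53 by 1.66 (SE 0.15) and Cd27 by 0.99 (SE 0.13) on the log2 scale. Of the hematopoietic stem cell markers 10 of 34 rose and 5 fell (10 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.305). The adjusted p by fry, which tests only whether members move one way on balance, was 0.00752, the low end of a range over the alternatives that reaches 0.45. Procr, the endothelial protein C receptor found on stem cells, was at 47.2, 59.2 and 62.5 CPM against 20.8, 20.5 and 23.4 CPM (log2 fold change 1.38, SE 0.16, adjusted p = 0.00122, edgeR). Krt18 rose (1.32, SE 0.22), and Tal1 (-1.22, SE 0.21) and Itga2b (-1.30, SE 0.15), which megakaryocytes also express, fell. Of the quiescence list 8 of 21 rose and 2 fell (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.0817, of 0.0358 without wildtype 3, and a range over the alternatives of 0.0016 to 0.347.

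In the myeloid lineage, several neutrophil granule genes rose. Of the neutrophil list 12 of 29 rose and 0 fell (12 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 3.8e-06). Adjusted p = 0.366 with an estimated correlation, against camera and fry values from 2.3e-13 to 0.0358 under the other alternatives. Lysozyme 2, Lyz2, was at 3048, 2103 and 2147 CPM against 673, 753 and 707 CPM (log2 fold change 1.77, SE 0.14, adjusted p = 2.1e-04, edgeR). Mmp8, a collagenase of neutrophil granules, changed by 2.73 (SE 0.35), lactoferrin, Ltf, by 1.54 (SE 0.19) and Ngp by 1.52 (SE 0.18) on the log2 scale. S100a8 (0.34, SE 0.37, adjusted p = 0.534, edgeR), S100a9 (0.41, SE 0.35, adjusted p = 0.419) and Camp (0.28, SE 0.35, adjusted p = 0.595), abundant transcripts of mature neutrophils, did not pass. These 3 and the B cell gene Ms4a1 (0.32, SE 0.43, adjusted p = 0.613, edgeR) are outside the naming rule and were chosen after their values were seen. Of the monocyte and macrophage list 5 of 27 rose and 0 fell (5 adjusted over the list alone, camera adjusted p = 0.433), among them Fcgr3 (1.53, SE 0.25) and Ctss (0.73, SE 0.14). Of the basophil, mast cell and eosinophil list 3 of 16 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.476), with Cpa3 at 1.22 (SE 0.16) and Gata2 at -0.68 (SE 0.12). Of the stroma and endothelium list 5 of 20 rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0582), with the matrix gene Postn at 3.29. Its adjusted p was 0.00157 without cluster KO 3 and 0.00167 without wildtype 2, over a range of 0.00157 to 0.515 under the alternatives.

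**Figure D3:**
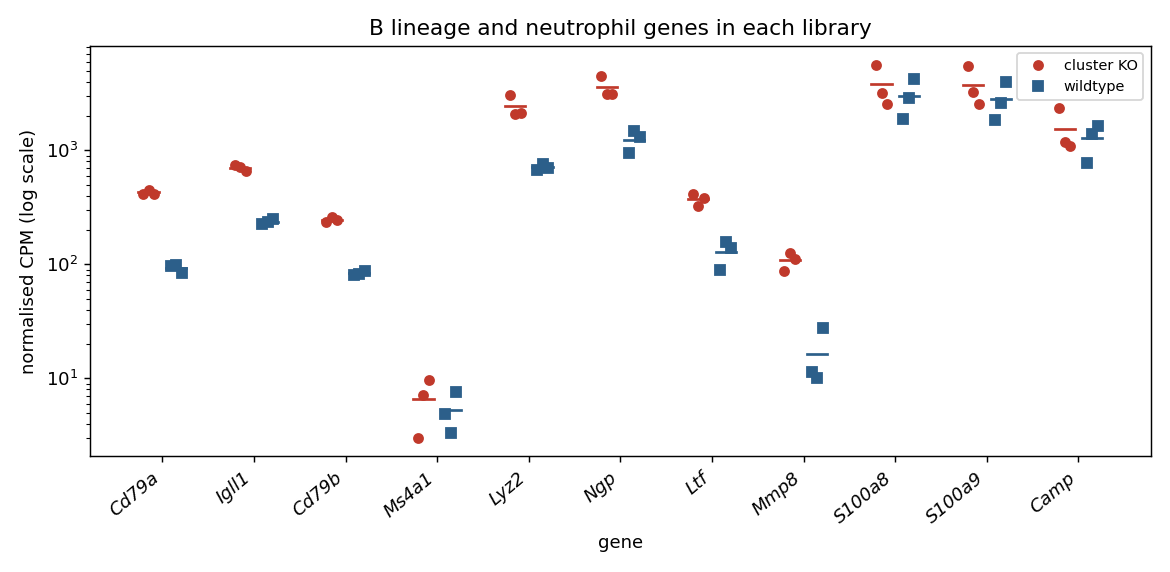
Normalised CPM (log axis) of B lineage and neutrophil genes in each library (circles, cluster KO; squares, wildtype; bars, means of 3 libraries). Cd79a, Igll1, Cd79b, Lyz2, Ngp, Ltf and Mmp8 show no overlap of the genotypes, while Ms4a1, S100a8, S100a9 and Camp overlap.

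The level of the erythroid list was lower in all 3 cluster KO libraries, and that of the megakaryocyte and platelet list was lower in 2 of them. Of the erythroid list 14 of 31 fell and 1 rose (15 and 2 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 2.8e-05). Adjusted p = 0.217 with an estimated correlation, against camera and fry values from 3.7e-07 to 0.00752 under the other alternatives. The membrane skeleton gene Add2 (-1.10, SE 0.14) and the blood group gene Ermap (-1.15, SE 0.13) fell. Of the heme synthesis list 4 of 14 fell and 2 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.837). Of the megakaryocyte and platelet list 6 of 21 fell and 4 rose (6 and 4 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.0406). Adjusted p = 0.437 with an estimated correlation, over a range that starts at 0.00537, and the list also missed the threshold without cluster KO 1 (camera adjusted p = 0.182) and by limma-voom with camera (adjusted p = 0.272). The list's level was -0.68, -0.02 and -0.21 in the cluster KO libraries, where cluster KO 2 lay within the wildtype range of -0.04 to 0.05. The list's median was -0.49 once length and GC trends were removed. Platelet factor 4, Pf4, fell (-1.86, SE 0.27) and the transcription factor gene Nfe2 rose, from 220, 201 and 178 CPM in wildtype to 322, 398 and 480 CPM.

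Several immediate early, glycolysis and lysosome genes were higher. Of the immediate early genes 10 of 20 rose and 0 fell (11 adjusted over the list alone, median 0.56, camera adjusted p = 5.4e-04), with adjusted p = 0.217 with an estimated correlation and camera and fry values from 1.9e-05 to 0.00586 under the other alternatives. The phosphatase gene Dusp1 changed by 1.91 (SE 0.26) and Junb by 1.40 (SE 0.22) on the log2 scale. Of the glycolysis genes 14 of 27 rose and 4 fell (15 and 4 adjusted over the list alone, median 0.59, camera adjusted p = 0.00301), with adjusted p = 0.391 with an estimated correlation and camera and fry values from 3.8e-05 to 0.0286 under the other alternatives. The glycolysis median was 0.38 once length and GC trends were removed. Enolase 1, Eno1, changed by 1.74 (SE 0.26) and Aldoa by 1.21 (SE 0.17). Of the autophagy and lysosome genes 18 of 46 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.36, camera adjusted p = 5.0e-04), with adjusted p = 0.391 with an estimated correlation and camera and fry values from 1.4e-06 to 0.0286 under the other alternatives. The cathepsin gene Ctsb changed by 1.15 (SE 0.19) on the log2 scale, and the autophagy protease gene Atg4b also rose (1.13, SE 0.18). In the cluster KO libraries the glycolysis list was at 0.37, 0.49 and 0.82 and the autophagy and lysosome list at 0.25, 0.37 and 0.57, at shares of reads outside genes of 10.05, 8.59 and 7.29%. In the wildtype libraries they were at 0.07, 0.04 and -0.04 and at 0.04, 0.03 and -0.05, at shares of 10.03, 10.50 and 11.06%. Of the NF-kappaB genes 7 of 24 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.0406), led by Il1rn (2.16, SE 0.35) and Nfkbia (0.70, SE 0.12; 0.38 once length and GC trends were removed). Adjusted p = 0.306 with an estimated correlation, over a range that starts at 0.00444, and the list missed the threshold by camera without cluster KO 1 (0.125), without wildtype 3 (0.0671), without cluster KO 3 and wildtype 3 together (0.0607), by limma-voom (0.0564) and once length and GC trends were removed (0.0826).

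The cell cycle lists did not pass. Of the G2/M genes 14 of 40 rose and 6 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.133), with Cdc20 at 0.95 (SE 0.19; 0.63 once length and GC trends were removed) and Cks2 at -0.77 (SE 0.11). Its adjusted p was 0.0295 without cluster KO 1, over a range of 0.0189 to 0.741 under the alternatives. Of the G1/S genes 9 of 41 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.462), with Rrm2 at 0.92 (SE 0.15) and Chaf1b at 1.22 (SE 0.23). By camera, the lists of the unfolded protein and integrated stress response (15 of 38 rose and 6 fell; 15 and 7 adjusted over the list alone), p53 targets (7 of 28 and 2; 7 and 2) and interferon response (13 of 47 and 2; 13 and 3) had adjusted p = 0.101, 0.208 and 0.325. The stress response list was at 0.0379 by camera without cluster KO 1 (range 0.0189 to 0.515), and the interferon list at 0.0358 by fry (range 0.0358 to 0.515). The lists of replication-dependent histones (1 of 33 rose and 3 fell, 1 and 3 adjusted over the list alone), imprinted genes (5 of 27 and 4, 5 and 4) and antioxidant genes (8 of 31 and 7, 8 and 8) had camera adjusted p = 0.358, 0.477 and 0.71. The heat shock (6 of 21 rose and 4 fell, 6 and 4 adjusted over the list alone) and mTORC1 (5 of 34 and 2, 5 and 2) lists had camera adjusted p = 0.744 and 0.759, and the mTORC1 list had a median of 0.03 with a mean of -0.01. With an estimated correlation 0 of the 37 lists passed in camera, 6 had an unadjusted p under 0.05, and fry called 20.

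The genotypes also differed in sex-linked transcripts. Xist, expressed from the inactive X chromosome, was at 1.92, 0.0842 and 1.58 CPM in the cluster KO and 228, 249 and 248 CPM in the wildtype libraries (log2 fold change -7.68, SE 0.54, adjusted p = 1.8e-04, edgeR), and its antisense partner Tsix was at -5.03 (SE 0.68). The Y chromosome genes were higher in cluster KO, with log2 fold changes of 2.56 (SE 0.27) for Eif2s3y, 1.97 (SE 0.18) for Ddx3y, 1.47 (SE 0.20) for Kdm5d and 1.45 (SE 0.19) for Uty. Each wildtype library held reads of Xist and of all 4 Y genes. The sex-linked list had 4 of 6 members higher and 2 lower (4 and 2 adjusted over the list alone), a median of 1.46, a mean of -0.88, a camera direction that was up and a camera adjusted p of 0.0582, which was 0.0376 without cluster KO 3 and 0.00844 without wildtype 3 (range over the alternatives 0.00408 to 0.64). No cluster KO library matched a wildtype library in Xist level, so genotype and this difference cannot be separated in any comparison above.

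**Figure D4:**
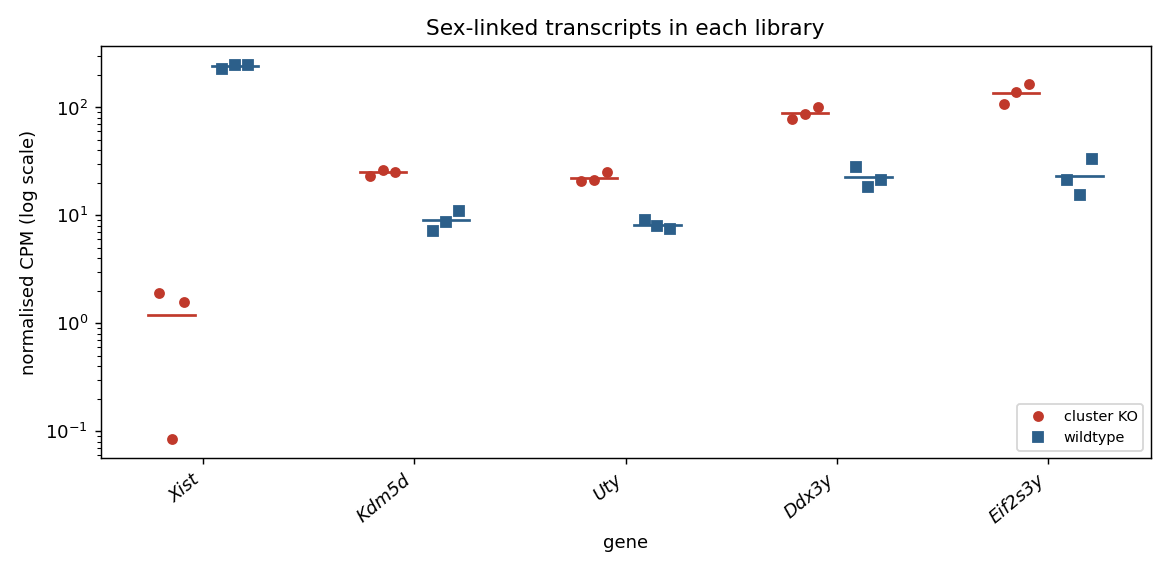
Normalised CPM (log axis) of Xist and 4 Y chromosome genes in each library (circles, cluster KO; squares, wildtype; bars, means of 3 libraries). Xist reaches 1.92 CPM at most in cluster KO and at least 228 CPM in wildtype libraries, and the Y genes are higher in cluster KO but present in each wildtype library.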

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

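The fits without length and GC trends, without X, Y and mitochondrial genes and without cluster KO 3 and wildtype 3 were chosen after seeing the data. Counts of higher and lower genes stayed within 1.5 times of 2487 and 1895 under both other scalings, both other count filters, the DESeq2 Wald test, the threshold of 0.1 and the fits without gene classes or trends. They were 3846 and 3535 by limma-voom, 984 and 453 with a fold change above 2, and 1303 and 852 without cluster KO 3 and wildtype 3. Leaving out 1 library gave 1258 to 3151 higher and 742 to 2579 lower genes, with a shift of over 1.5 times without cluster KO 2, wildtype 2 or wildtype 3. No gene called in the main comparison was called in the other direction under any of the 17 gene-level alternatives. Lists numbered 8 higher and 8 lower, 13 higher with no count filter, and 8 to 10 higher and 7 to 8 lower with 1 library left out. With an estimated correlation camera called 0 lists in each direction, where 6 had an unadjusted p under 0.05 and fry called 12 higher and 8 lower. Fewer libraries lower the power of the smaller fits, and the cause of the other shifts was not tested.

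The replicate numbers did not pair the libraries: same-numbered libraries correlated in their deviations from the genotype means at -0.122, 0.015 and -0.089, and only replicate 2 correlated best with its own number. With the replicate block, 1159 genes were higher and 705 lower.

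Among values of the 135 named genes under the alternatives, 2217 kept their side of the threshold and 56 kept their direction but missed it. Among values of the 37 lists, 612 kept their side, 24 fell short of the threshold and 27 newly passed it. Values not called either way changed sign 2 times for genes and 13 times for lists, and the medians of the ribosome biogenesis, monocyte, heme synthesis and histone lists changed sign once trends were removed. Depth limits the locus, where Rian and Mirg were under the count filter.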

Other observations

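Tests of sex-linked genes, sex of autosomal calls, mixed sexes, pseudogene reads, cell type shares and other splits of the libraries were chosen only after the result was seen, as were the lists of B cell stages, clock genes and X genes that escape inactivation, and the genes named here outside the rule.

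Of 17 tested core clock genes 4 rose and 2 fell, and the list did not pass the tests for a shift in 1 direction. Per1 (log2 fold change -2.04, SE 0.24) and Per2 (-0.63, SE 0.20) were lower, while Arntl (0.75, SE 0.17), Dbp (1.10, SE 0.25) and Nfil3 (1.77, SE 0.39) were higher by the edgeR test. By camera the unadjusted p of the list was 0.505, and by fry 0.0635. The fry test for change in either direction gave 0.00122, adjusted over the lists added after the result was seen. Of 13 genes of B cell precursors 12 rose (median 1.49), among them Blnk (2.13, SE 0.17) and Vpreb1 (1.49, SE 0.12), while 2 of 13 mature B cell genes, Ccr7 (1.89, SE 0.50) and Fcmr (1.96, SE 0.58), rose (median 0.49). The unadjusted p of the mature list was 0.0241 by fry and 0.113 by camera. The B lineage list of the report holds 12 of the precursor and 8 of the mature genes. Of 7 X genes that escape inactivation 3 fell, Kdm6a (-1.12, SE 0.15), Eif2s3x (-1.01, SE 0.11) and Kdm5c (-0.58, SE 0.17). By camera the unadjusted p of that list was 5.3e-04, and by fry 3.0e-05. Of all tested X genes 26.6% were called, against 28% of autosomal genes (two-sided Fisher's exact p = 0.509).

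Elane, a primary granule protease gene, was at 710, 2.19 and 171 CPM in the cluster KO libraries and at 251, 296 and 113 CPM in wildtype. Igkc was at 36.3, 2108 and 53.4 CPM in cluster KO and at 1299, 1428 and 1046 CPM in wildtype. Of 12 genes called with a log2 fold change under -4, 8 were pseudogenes, among them Gm15772 (-8.67). The 12 lie on 7 chromosomes, and why they were near absent in cluster KO was not tested. The 4 that were not pseudogenes were Xist, Tsix, AA465934 (-6.51, at 2.28, 1.05 and 1.35 CPM against 120, 139 and 168 CPM) and the chemokine gene Ccl8 (-4.35, at 0.0, 0.21 and 0.0 CPM against 3.08, 0.566 and 1.13 CPM). Of 15 called above 4, 0 were pseudogenes, and 5 of the called genes had 0 counts in every wildtype library: Tmem45a2 at least 9.33-fold higher in cluster KO, Galnt9 7.67-fold, Serpina3c 7.40-fold, Ighv1-64 4.53-fold and Sult5a1 4.25-fold, each bound set against the mean floor of 3 counts per wildtype library.

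The genes called between the genotypes may owe to sex as well as to the deletion, and library quality stays open for them too. Of the variance between libraries in log2 CPM, 50.2% lay on the first principal component. Positions on it followed the share of reads outside genes within each genotype. In cluster KO they were -22.2, -48.1 and -69.8 at 10.05, 8.59 and 7.29%. In wildtype they were 35.7, 44.9 and 59.6 at 10.03, 10.50 and 11.06%. Cluster KO 1 and wildtype 1 lay apart at a near equal share, which rests on 1 pair. Xist (log2 fold change -7.68) and the 4 Y genes moved as a sex difference requires, and Y genes at 0.11 or more of their cluster KO mean in each wildtype library, beside Xist above 100 CPM, is consistent with wildtype libraries that hold cells of both sexes. For autosomal calls genotype and sex cannot be told apart, since 0 of the 9 pairs of a cluster KO and a wildtype library lie on the same side of 50 CPM of Xist. For the 47 of 4382 called genes within 10 Mb of Rian, flanking DNA stays open too: 33.3% of the 141 tested genes there were called (95% exact interval 25.6 to 41.8) against 27.9% elsewhere (two-sided Fisher's exact p = 0.158). That share does not weigh the size of the changes. Among the genes called above a log2 fold change of 4, Serpina3c (7.56), Ighv1-64 (6.86), Ighv5-2 (6.79) and Ighv1-53 (5.20) lie in this window. Ighg2b, which fell (-2.72), lies there too. Of the 10 splits of the 6 libraries, the real one included, with counts in either direction, 1 gave as many genes as the 2487 higher and 1 as many as the 1895 lower (highest other 1 for both), while 2 gave as many lists as the 8 higher and 2 as many as the 8 lower (highest other 8), and 10 splits are too few for a share under 0.05.

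The fall of ribosomal protein genes, with a median log2 fold change of -0.86 over 79 genes, lay below the range of -0.43 to -0.10 that held the middle 95% of 10000 random lists matched on length and expression, which argues against transcript length bias as the whole cause. Lists matched on length alone had a median of 0.01, with the middle 95% from -0.16 to 0.20. The random lists were drawn gene by gene and not matched on GC content. Their range leaves out the correlation among ribosomal protein genes (estimated at 0.78 and 0.94 for the large and small subunits) and may be too narrow. Once length and GC trends were removed the ribosomal protein median was -0.76, with 79 of 79 genes called lower by edgeR against 77 before. Reads lost to near-identical pseudogenes stay open. The share of reads with more than 1 alignment was 2.45 percentage points lower in cluster KO (a difference of -2.45), lower in each cluster KO than in each wildtype library. That share pools the reads of all genes, the fallen ribosomal protein genes among them. It therefore cannot show whether reads of ribosomal protein genes were lost to their copies. RNA or library quality stays open: within each genotype the ribosomal protein level followed the share of reads outside genes (-0.63, -0.90 and -1.09 at 10.05, 8.59 and 7.29% in cluster KO, -0.09, -0.04 and 0.14 at 10.03, 10.50 and 11.06% in wildtype), yet cluster KO 1 and wildtype 1 differed by -0.54 on the log2 scale at a near equal share, a gap that rests on 1 pair, and the share of counts on rRNA genes ran in the same order as the level within each genotype (0.614, 0.383 and 0.251%, and 0.998, 1.08 and 1.44%). The loss of the cluster, and the sex difference, are the untested biological candidates.

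A lower share of the main cell type could lie behind the rise of B lineage and neutrophil genes. It would raise the markers of other types alike. The B lineage median lay 1.27 above the T and NK median (95% bootstrap interval 0.45 to 1.75), so these lists did not rise alike. Other cell type lists had medians above 0, such as dendritic cells (0.83), early progenitors (0.80) and plasma cells (0.52). The erythroid (-0.39) and megakaryocyte (-0.29) lists had medians below 0. The main cell type is not known, so this contrast leaves a lower share open for the B lineage. The bootstrap resampled genes, not libraries, and the B lineage was compared because it had risen. The T and NK level was 0.501, 0.118 and -0.355 in the cluster KO libraries. Neutrophil genes were not compared in this way, and for them a lower share also stays open. Mature B cells mixed into the cluster KO samples stay open: the precursor median lay 1 above the mature median (interval 0.38 to 1.29), but 12 of the 13 precursor genes are on the B lineage list itself, and the mature list had a median of 0.49 with several genes at a few CPM. Mature neutrophils mixed in stay open, since the changes of S100a8 and S100a9 have upper 95% bounds of 1.20 and 1.23, above the neutrophil list median of 0.65, and Ngp, another abundant transcript, rose by 1.52. The loss of the cluster and the sex difference are untested here. The labels name no sort or depletion, but globin genes took 0.027 and 0.068% of the counts in cluster KO and wildtype, and whether such a step set the share of these cells is not given in the sources used here.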
